A study of Homo sapiens with 6 samples.

How the data were processed

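Primary human hepatic stellate cells were sequenced in 6 libraries, 3 from cells transfected with an esiRNA against EPHB2 and 3 from cells transfected with an esiRNA against eGFP as nontargeting control. An esiRNA is a pool of short double-stranded RNAs made by enzymatic digestion of a longer one. Per the labels' protocols, the cells were used at passages 2 to 6, incubated for 48 h after transfection and then stimulated with TGF-beta1 at 10 ng/ml for 24 h. Total RNA was depleted of ribosomal RNA and made into stranded libraries with a TruSeq kit, per the labels' protocols.

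The authors deposited 1 table of raw gene counts, whole numbers for 60664 Ensembl gene identifiers in the 6 libraries, and per the file headers each column holds the counts of 1 library. The submitters' processing notes name STAR 2.7.6a, featureCounts 1.6.3, DESeq2 1.30.0 and the human build GRCh38. The annotation release, the strand setting of the counting and any read filters are not given in the sources used here. Genes that overlap an antisense neighbour, and genes with near-identical copies such as the metallothioneins and the class I HLA genes, are therefore uncertain in level. Each column name carries the library code that stands in 1 sample title, and every column was assigned by that code. Of the identifiers, 60463 matched the gene name table and 58396 matched GENCODE release 29, which was used for coordinates and gene types on the same build. Genes on the Y chromosome and XIST stayed in the fits and are not reported by name.

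Library totals ran from 24699377 to 34614863 counts. Counting error is small at this depth for genes well above 1 CPM (counts scaled to the library total), and the spread between libraries sets the precision of their comparisons. Near or below 1 CPM counting error adds to that spread. The labels do not say whether the 3 libraries of a group came from separate cultures, platings or donors, so p-values measure only the spread between these libraries, which may be technical.

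The main test was fixed before the data were examined. It was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, with genes filtered by filterByExpr (minimum count 10), TMM scaling, robust dispersion and Benjamini-Hochberg adjustment over all 15343 tested genes at 0.05. The contrast was EPHB2 esiRNA minus control esiRNA over all 6 libraries, with no covariate. Levels are TMM-scaled CPM, and log2 CPM used a prior count of 2. Standard errors (SE) of log2 fold changes were taken from the fold change and its quasi-likelihood F statistic.

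A second fit was chosen after seeing the data. The first principal component of log2 CPM divided the libraries across the groups, into set 1 (control replicate 1 and EPHB2 esiRNA replicates 2 and 3) and set 2 (control replicates 2 and 3 and EPHB2 esiRNA replicate 1). This library set was added as a term, and log2 differences between the groups were also computed within each set. The labels give no batch, culture or donor that accounts for the sets. The fit with the term has 3 residual degrees of freedom, from the pair of controls in set 2, the pair of EPHB2 esiRNA libraries in set 1 and the difference between the sets. The library sets are not groups of the study. Because the term was derived from the same counts that it was then fitted to, p-values with the term may be too small by an amount not estimated here.

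26 gene lists with 696 entries were written before the data were examined. They cover TGF-beta response genes, collagens, matrix glycoproteins and proteoglycans, collagen folding and crosslinking enzymes, matrix proteases, contractile genes, quiescent stellate cell genes, Eph receptors and ephrins, TGF-beta and PDGF ligands and receptors, and YAP/TAZ and SRF targets. Others cover cell division, DNA replication, interferon-stimulated genes, NF-kB and inflammatory cytokine genes, unfolded protein and integrated stress response genes, cholesterol synthesis, p53 targets, hypoxia and glycolysis, axon guidance, RNA interference machinery and mitochondrial transcripts. The rest are markers of hepatocytes, endothelial cells, macrophages and leukocytes, cholangiocytes, and smooth muscle cells and portal fibroblasts. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, which compares a list with the other genes, with Benjamini-Hochberg adjustment over the 26 lists. Camera with an estimated correlation and fry, which asks whether a list moves on balance one way, stand beside it. A camera p at the preset may be far too small where the correlation within a list is above 0.01. The estimated correlations rest on 4 residual degrees of freedom, or 3 with the library set term. Members past the threshold were counted over all genes tested and adjusted over the list alone.

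Named genes followed a rule fixed before the data were examined. It takes EPHB2, and the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. It adds 14 fixed fibrosis and TGF-beta genes, and up to 4 members of smallest p from each list with a member past the threshold. A list with none gives up to its 2 most abundant members. List members named because they passed in the fit with the library set term were picked by that rule in a fit chosen after seeing the data. Some genes that the rule takes are not reported here.

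Alternatives fixed before the data were examined were RLE size factors or library totals in place of TMM, no low-count filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, a minimum fold of 1.2 (glmTreat), a replicate block, and leaving out each library. Added after seeing the data were the library set term, its own set of alternatives, and 1 surrogate variable from svaseq (sva 3.50.0). A gene with 0 counts in all 3 control libraries is given as a lower bound, against a floor of 3 counts over the control group.

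Both fits were tested on simulated counts for the EPHB2 esiRNA contrast, drawn for 15343 genes, of which 15146 were tested. The counts followed the real means and library sizes and the dispersions of the fit with the term, with the library sets kept as observed. In them 200 genes were changed, all with a mean of at least 5 CPM, so recovery at lower levels was not covered. The test without the term recovered 2 of 100 genes changed 2-fold and 67 of 100 changed 4-fold, and called 0 unchanged genes. The test with the term recovered 71 and 99 of 100 and called 15 unchanged genes. The simulation gave the fit the true sets, so it does not cover the choice of the sets from the data. Figures were drawn with matplotlib 3.10.9.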

Results

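RNA was counted per gene in cultured primary human hepatic stellate cells, the vitamin A storing pericytes of the liver that turn into matrix-producing myofibroblasts on activation. The question was how loss of EPHB2, a receptor tyrosine kinase for ephrin-B ligands, alters cells activated by TGF-beta1. All 6 libraries came from stimulated cells, 3 with control esiRNA and 3 with EPHB2 esiRNA, so the response to TGF-beta1 itself was not measured. The titles call the groups wild type and knockout, whereas the protocol describes esiRNA transfection, and the groups are named here by reagent. Total counts were 33923522, 29977571 and 34614863 in control replicates 1 to 3 and 28451441, 24699377 and 30801819 in EPHB2 esiRNA replicates 1 to 3. FN1, the gene of fibronectin, was the most abundant gene in every library, at 2.699% to 5.951% of counts.

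EPHB2 was lower in every EPHB2 esiRNA library than in every control library. This protein-coding gene (ENSG00000133216) lies on the plus strand of chromosome 1, from 22710839 to 22921500 in GRCh38. Its level was 167 ± 15.2 CPM in controls and 31.6 ± 13.8 CPM with EPHB2 esiRNA (SD, n = 3 each), or 18.9% of the control mean. Control replicates 1 to 3 had 152, 168 and 182 CPM, and EPHB2 esiRNA replicates 1 to 3 had 47.6, 24.5 and 22.9 CPM. The residual level was thus 28.4% of the control mean in replicate 1 and 14.6% and 13.7% in replicates 2 and 3. The log2 fold change was -2.40 (SE 0.32), and the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.0626, which misses the threshold. With the library set term, chosen after seeing the data, the log2 fold change was -2.28 (SE 0.19) and the adjusted p from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00353. The call was also made without control replicate 1 (log2 fold change -2.47) and without EPHB2 esiRNA replicate 1 (-2.82), and by DESeq2 at an adjusted p of 5.11e-09.

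**Figure D1:**
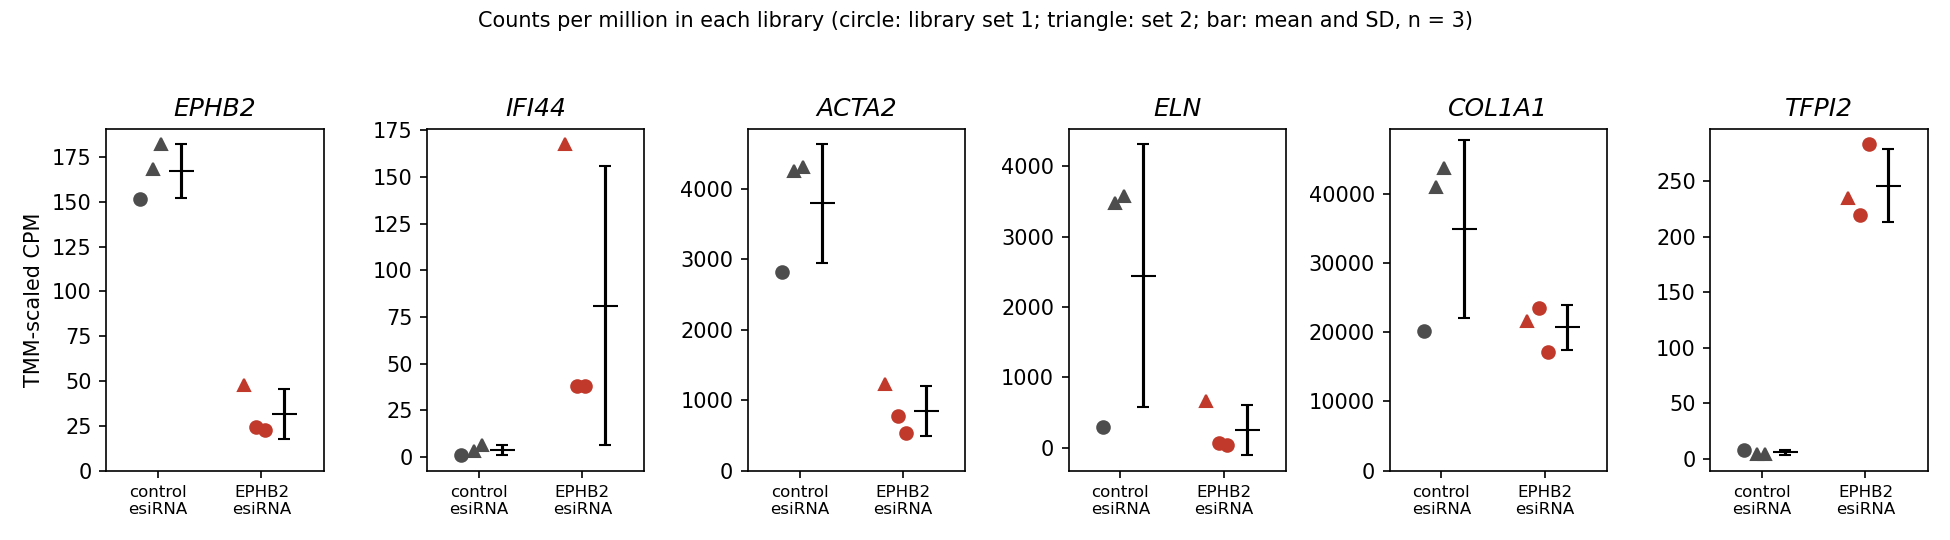
TMM-scaled CPM of 6 genes in each library, by group, with circles for library set 1, triangles for library set 2, and bars for the mean and SD (n = 3). EPHB2 was between 152 and 182 CPM in controls and between 22.9 and 47.6 CPM with EPHB2 esiRNA, and ELN shows the division of the controls into the library sets.

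The libraries divided across the groups. The first principal component, with 49.6% of the variance of log2 CPM, placed control replicate 1 with EPHB2 esiRNA replicates 2 and 3, and control replicates 2 and 3 with EPHB2 esiRNA replicate 1. The second, with 35.6%, separated the groups, with scores of -45.0 to -28.7 in controls and of 7.99, 9.92 and 89.0 in EPHB2 esiRNA replicates 2, 3 and 1. Control replicate 1 correlated across genes at r = 0.969 and 0.964 with EPHB2 esiRNA replicates 2 and 3, and at 0.949 and 0.948 with the other controls. EPHB2 esiRNA replicate 1 correlated at 0.933 and 0.936 with control replicates 2 and 3, and at 0.932 and 0.924 with EPHB2 esiRNA replicates 2 and 3. By these correlations its place in set 2 had a small margin only. Control replicates 2 and 3 were the closest pair (r = 0.994), with a chi-square per degree of freedom of 3.93. It was 31.3 for EPHB2 esiRNA replicates 2 and 3 and between 90.5 and 469 for the other pairs. The value of 3.93 is above sampling noise, and the libraries were kept as separate. Whether they came from separate cultures is not known, and the control SDs and the fit with the set term rest in part on this close pair. Mitochondrial messenger RNAs took 4.46%, 2.23% and 2.25% of counts in control replicates 1 to 3 and 1.52%, 4.73% and 4.84% in EPHB2 esiRNA replicates 1 to 3, a division along the sets.

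**Figure D2:**
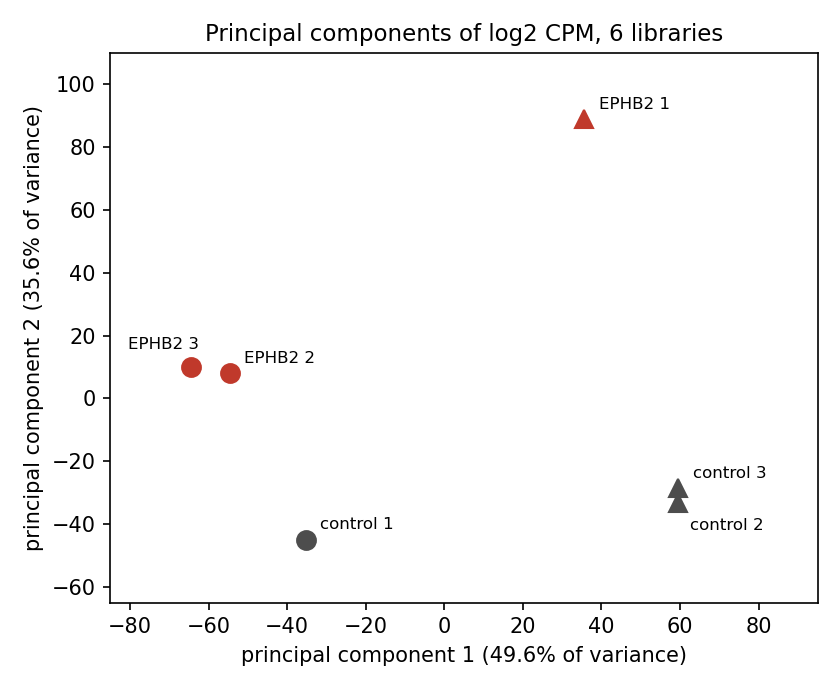
The first and second principal components of log2 CPM for the 6 libraries, in units of the component scores, with grey for control esiRNA, red for EPHB2 esiRNA, circles for library set 1 and triangles for library set 2. The first component, with 49.6% of the variance, separates the sets, and the second, with 35.6%, separates the groups.

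TFPI2, a secreted serine protease inhibitor, showed the largest rise with EPHB2 esiRNA among the 10 rises named from the test without the library set term, from 5.67 ± 2.26 to 246 ± 33.0 CPM (SD, n = 3 each). ITGA2, the collagen-binding integrin alpha 2 chain, rose from 50.8 ± 8.41 to 356 ± 46.6 CPM, and NT5E (CD73), a surface enzyme that makes adenosine, from 125 ± 30.3 to 780 ± 228 CPM. PHLDA1, the thiol transferase GLRX, the neuropilin-like receptor DCBLD2, the stress kinase MAPK13, SLC6A15, FAM167A and TMEM156 rose too, with log2 fold changes from 1.82 for DCBLD2 to 4.21 for TMEM156. CEMIP, which takes part in hyaluronan breakdown, fell from 72.8 ± 31.6 to 7.83 ± 0.51 CPM, and the kinase gene PIM1 from 28.0 ± 1.22 to 8.41 ± 1.30 CPM. CEMIP had the largest of the 6 named falls, at a log2 fold change of -3.22, and HSD17B6, ILDR2, CHML and PNMA2 also fell.

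Of 15343 genes tested with edgeR, 20 rose and 10 fell, and 2392 had an unadjusted p under 0.05. The smallest Benjamini-Hochberg adjusted p of the edgeR quasi-likelihood test was 0.0338, for TFPI2, with a log2 fold change of 5.44 (SE 0.35). In all 30 genes the groups did not overlap, and over all tested genes this held for 22.4%, where chance gives 10%. Without control replicate 1 the counts were 202 and 165, without EPHB2 esiRNA replicate 1 they were 192 and 93, and without any 1 of the other 4 libraries they were 0 and 0, with 1250 to 1822 genes at an unadjusted p under 0.05. DESeq2 called 545 genes higher and 419 lower.

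The fit with the library set term was chosen after seeing the data, and its p-values take no account of that choice. In it 913 genes rose and 801 fell, and the 30 genes of the test without the term were all among them. NT5E had log2 differences of 2.85 in set 1 and 2.87 in set 2, ITGA2 of 2.99 and 2.87, and CEMIP of -3.74 and -2.89. The numbers of genes higher and lower were 2828 and 2896 without control replicate 1, 197 and 174 without control replicate 2, and 175 and 168 without control replicate 3. They were 1225 and 1238, 325 and 305, and 283 and 204 without EPHB2 esiRNA replicates 1, 2 and 3. Of the 93 named genes past the threshold with the term, 40 passed in all 6 of these fits. Among them were EPHB2, TFPI2, ITGA2, NT5E, ACTA2, MYLK, MYH10, ELN, COL8A2, MX2 and IFI44. Many of the 93 were named for a small p in this same fit, so this share does not carry over to all genes called. Without control replicate 1 or EPHB2 esiRNA replicate 1 the contrast rests on 1 set, with a single library on 1 side, so these fits are weak checks.

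**Figure D3:**
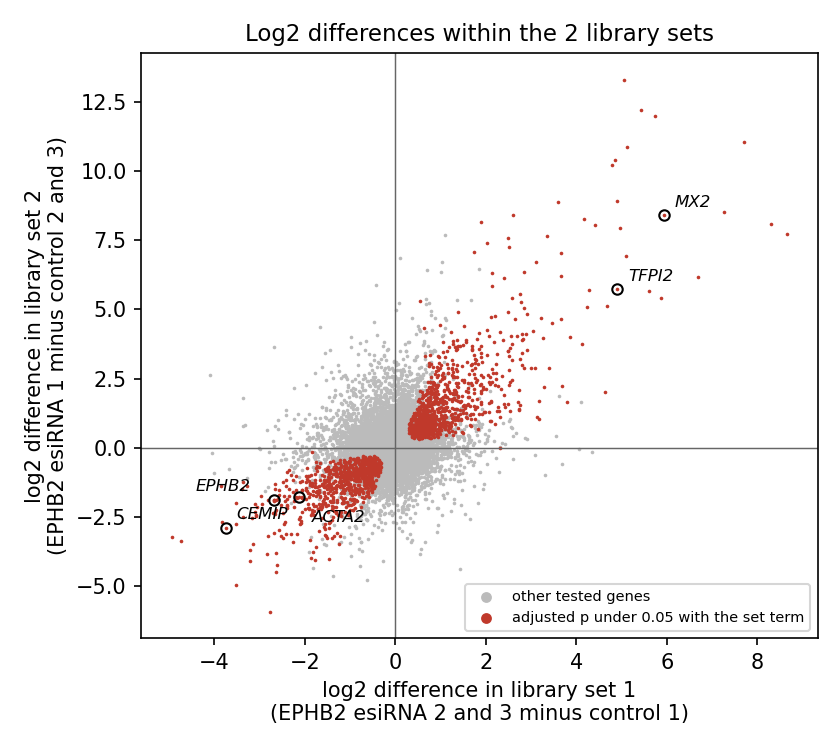
Log2 differences (EPHB2 esiRNA minus control esiRNA) of each tested gene within library set 1, on the horizontal axis, and within library set 2, on the vertical axis, with red for genes past the threshold in the fit with the library set term. TFPI2 and MX2 lie above 0 in both sets, and EPHB2, ACTA2 and CEMIP below 0 in both.

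Interferon-stimulated genes were higher with EPHB2 esiRNA in both library sets. Of the 41 tested members 39 rose and 0 fell with the library set term, and the median log2 fold change was 4.92, also with CXCL11 at its lower bound. IFI6 went from 32.0 ± 11.9 to 1020 ± 1081 CPM (SD, n = 3 each), with log2 differences of 3.66 in set 1 and 6.22 in set 2. MX2, an antiviral GTPase, rose by 8.32 and IFI44 by 4.92 on the log2 scale. CXCL11, a chemokine gene, had 0 counts in the 3 control libraries and 90.6 ± 151 CPM with EPHB2 esiRNA, at least 2890-fold higher against a floor of 3 counts over the control group. EPHB2 esiRNA replicates 1 to 3 had 265, 3.64 and 3.25 CPM of it, and without replicate 1 the gene was at least 110-fold higher. The mean log2 CPM of the list was 1.30, 1.61 and 2.43 in control replicates 1 to 3 and 8.20, 5.25 and 4.93 in EPHB2 esiRNA replicates 1 to 3. In the edgeR test without the term 0 members passed over all genes, 40 passed adjusted over the list alone, 40 had an unadjusted p under 0.05 and DESeq2 called 26. All 41 passed adjusted over the list alone with the term. The list had a camera p with Benjamini-Hochberg adjustment of 3.65e-28, against an adjusted p = 0.451 with an estimated correlation and 0.0701 by fry. With the term these were 1.01e-27, 0.435 and 0.0366, and 22 members rose without control replicate 3. The estimated correlation of the list was 0.854, and 0.766 with the term, against the preset 0.01. Its very small camera p-values therefore rest on the preset.

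Contractile and actin cytoskeleton genes fell in part with EPHB2 esiRNA. Of 41 members 12 fell with the library set term, 2 rose and 27 did not pass, and the median log2 fold change was -0.58. ACTA2, which encodes the alpha smooth muscle actin of activated stellate cells, went from 3790 ± 849 to 847 ± 352 CPM (SD, n = 3 each), with log2 differences of -2.12 in set 1 and -1.80 in set 2. The myosin light chain kinase gene MYLK fell by 1.74, the myosin gene MYH10 by 1.58 and the desmin gene DES by 2.73 on the log2 scale with the term. TAGLN (transgelin) fell by 0.88, whereas the abundant members ACTB and FLNA, at log2 fold changes of -0.07 and -0.65, did not pass. PXN and ITGA5, named after their values were seen, were the members that rose. ACTA2 did not pass in the edgeR quasi-likelihood test without the term (Benjamini-Hochberg adjusted p = 0.0824, log2 fold change -2.16, SE 0.39). In that test 0 members passed over all genes, 6 lower and 1 higher passed adjusted over the list alone, 21 lower and 2 higher had an unadjusted p under 0.05, and DESeq2 called 15 lower and 1 higher. Adjusted over the list alone with the term, 19 were lower and 2 higher. The list's camera adjusted p with Benjamini-Hochberg adjustment was 7.52e-08, against an adjusted p = 0.472 with an estimated correlation and 0.0701 by fry, and with the term 3.05e-06, 0.663 and 0.12. The number that fell was 21, 5 and 4 without control replicates 1, 2 and 3, and 6 without EPHB2 esiRNA replicate 3, and at most 1 member rose without control replicate 2 or 3 or EPHB2 esiRNA replicate 2.

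Smooth muscle and portal fibroblast markers fell in part too. DES, MYH11, CNN1, LMOD1 and SYNPO2 stand in both lists, and FBLN2 and MFAP5 also stand in the matrix glycoprotein list. The result is therefore not separate from those of the other lists. With the term 5 of the 11 tested markers fell and 0 rose, and 8 were lower adjusted over the list alone. MYH11, the smooth muscle myosin heavy chain gene, went from 663 ± 452 to 29.6 ± 22.6 CPM (SD, n = 3 each). For these markers the camera adjusted p with Benjamini-Hochberg adjustment was 0.00277, against an adjusted p = 0.205 with an estimated correlation and 0.0207 by fry, and with the term 0.000478, 0.435 and 0.0366. Without control replicate 1 the camera adjusted p was 0.0553, and 0.0703 with the term, and the number that fell was 2, 1, 1 and 3 without control replicates 2 and 3 and EPHB2 esiRNA replicates 2 and 3.

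Genes of the TGF-beta response list moved down with EPHB2 esiRNA in part. Of 39 members 12 fell with the library set term, 0 rose and 27 did not pass, and the median log2 fold change was -0.45. ELN, the elastin gene, fell by 2.51 on the log2 scale, with differences of -2.67 in set 1 and -2.40 in set 2. LMCD1, the metalloprotease gene ADAM19 and DACT1 fell by 0.92, 0.95 and 0.68. TGFBI and CCN2 (connective tissue growth factor) did not pass, at log2 fold changes of 0.08 and -0.63 with the term. In the edgeR test without the term 0 members passed over all genes, 4 lower passed adjusted over the list alone, 8 lower had an unadjusted p under 0.05 and DESeq2 called 6 lower. Adjusted over the list alone with the term, 15 were lower. The camera adjusted p of the list with Benjamini-Hochberg adjustment was 0.0112, against an adjusted p = 0.535 with an estimated correlation and 0.236 by fry, and with the term 0.00234, 0.663 and 0.12. Without EPHB2 esiRNA replicate 1 the camera adjusted p was 0.205, and 0.299 with the term. The number that fell with the term was 21, 1 and 1 without control replicates 1, 2 and 3, and 6 and 2 without EPHB2 esiRNA replicates 2 and 3. Without EPHB2 esiRNA replicate 1, 13 fell and 6 rose, and without control replicate 1, 2 rose.

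Collagen genes went both ways. Of 23 collagens 4 fell with the library set term and 3 rose, and 16 did not pass. COL8A2 fell by 2.72 and COL14A1 by 1.41 on the log2 scale, and COL5A3 and COL24A1 rose by 1.08 and 0.92. The fibrillar collagen genes COL1A1, COL1A2 and COL3A1 did not pass, with log2 fold changes of -0.48 (SE 0.32), -0.21 (SE 0.23) and -0.56 (SE 0.20). COL1A1 had 34950 ± 12910 CPM in controls and 20740 ± 3253 CPM with EPHB2 esiRNA (SD, n = 3 each). Its log2 difference was -0.00 in set 1 and -0.97 in set 2. In the edgeR test without the term 0 collagens passed over all genes, 1 lower passed adjusted over the list alone, 8 lower and 1 higher had an unadjusted p under 0.05, and DESeq2 called 4 lower and 1 higher. Adjusted over the list alone with the term, 5 were lower and 4 higher. The collagen list had a camera adjusted p with Benjamini-Hochberg adjustment of 0.0635, and of 0.427 with the term. It passed without control replicate 1 (0.00101, and 0.0292 with the term) and without EPHB2 esiRNA replicate 2 (0.0336), and with the term 12, 1 and 1 collagens fell without control replicates 1, 2 and 3 and 2 without EPHB2 esiRNA replicate 2 or 3. The number that rose was 5 without control replicate 1 or EPHB2 esiRNA replicate 1, and at most 1 without any 1 of the other 4 libraries.

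Of the matrix glycoproteins and proteoglycans, 7 of 34 fell and 1 rose with the library set term, and the median log2 fold change was -0.48. Besides ELN, the small proteoglycan gene BGN fell by 1.14 and the thrombospondin gene THBS2 by 1.55 on the log2 scale, and MFAP5 fell near the detection floor, from 1.28 to 0.34 CPM. NID2, named after its values were seen, rose. FN1 and SPARC, the most abundant members, did not pass, with log2 fold changes of -0.44 (SE 0.28) and -0.52 (SE 0.19). In the edgeR test without the term 0 members passed, 0 passed adjusted over the list alone, 6 lower and 1 higher had an unadjusted p under 0.05, and DESeq2 called 5 lower. Adjusted over the list alone with the term, 10 were lower and 1 higher. By camera with Benjamini-Hochberg adjustment the list had an adjusted p of 0.00277, against an adjusted p = 0.205 with an estimated correlation and 0.0207 by fry, and with the term 0.000478, 0.435 and 0.0422. The number that fell was 16, 2 and 2 without control replicates 1, 2 and 3, and 12, 4 and 1 without EPHB2 esiRNA replicates 1, 2 and 3. The number that rose was 4 without control replicate 1 or EPHB2 esiRNA replicate 1.

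Collagen folding and crosslinking enzymes also went both ways, with 2 of 25 lower and 3 higher with the term, the same numbers as adjusted over the list alone. The lysyl oxidase genes LOX and LOXL1 fell by 0.89 and 0.51 on the log2 scale, while LOXL3 and P3H2 rose by 0.92 and 0.73. By camera the list had a Benjamini-Hochberg adjusted p of 0.533, and of 0.568 with the term. Without control replicate 1 the numbers were 10 lower and 5 higher, and without any 1 of control replicates 2 and 3 and EPHB2 esiRNA replicates 2 and 3 at most 1 member passed.

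**Figure D4:**
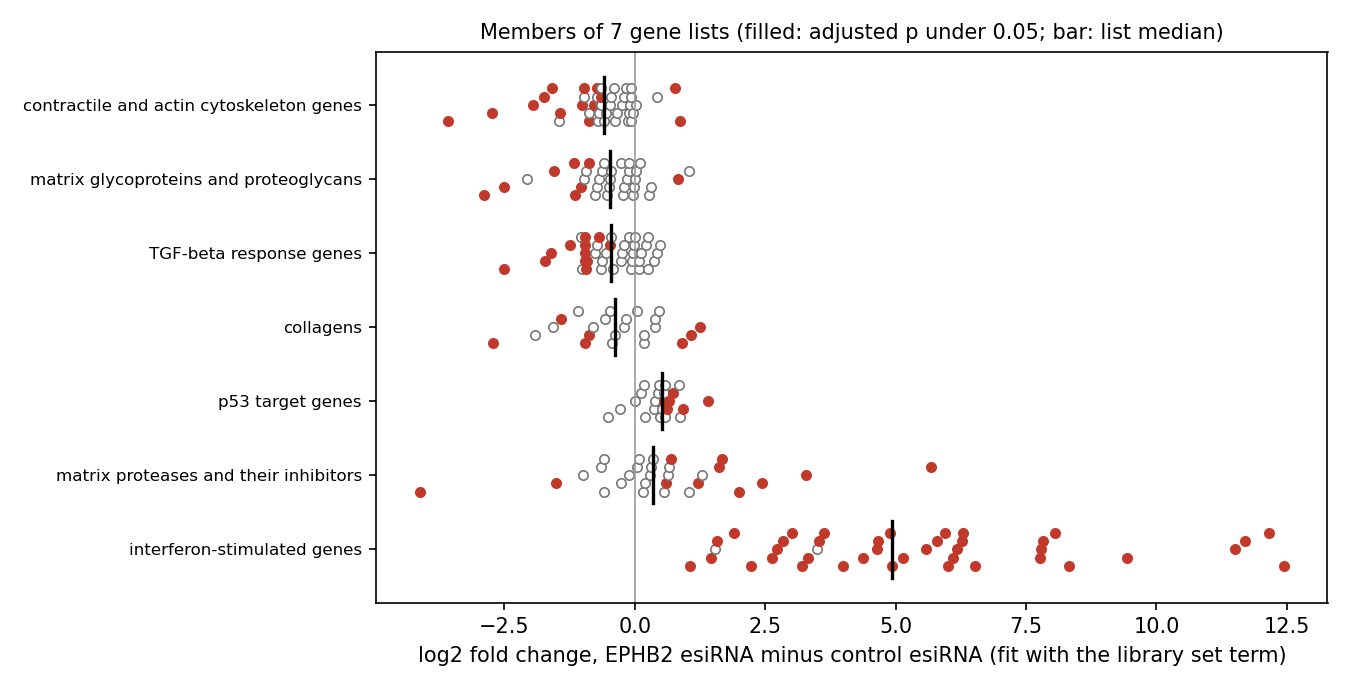
Log2 fold changes (EPHB2 esiRNA minus control esiRNA, fit with the library set term) of the tested members of 7 gene lists, with filled points for an adjusted p under 0.05 and black bars for list medians. The interferon list has a median of 4.92, the contractile list of -0.58, and CXCL11, at 0 counts in controls, is drawn at its lower bound.

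Matrix proteases and plasminogen activator genes rose in part with EPHB2 esiRNA. Of 29 members 9 rose and 2 fell with the library set term, and 14 were higher and 4 lower adjusted over the list alone. MMP1, interstitial collagenase, went from 4.30 ± 3.26 to 116 ± 134 CPM (SD, n = 3 each), with log2 differences of 5.86 in set 1 and 5.43 in set 2. The urokinase receptor gene PLAUR, the urokinase gene PLAU and PLAT, tissue plasminogen activator, rose by 1.62, 1.68 and 1.22 on the log2 scale. ADAMTS9 and MMP24, named after their values were seen, fell. TIMP1, an inhibitor of matrix metalloproteases, did not pass, at a log2 fold change of 0.63 (SE 0.22). Camera gave the list a Benjamini-Hochberg adjusted p of 0.00205, against an adjusted p = 0.205 with an estimated correlation and 0.0207 by fry, and with the term 0.00234, 0.435 and 0.035. With the term the camera adjusted p was 0.0599 without control replicate 1, and the number that rose was 14, 3 and 4 without control replicates 1, 2 and 3 and 5 without EPHB2 esiRNA replicate 2 or 3. The number that fell was 6 without control replicate 1 and 5 without EPHB2 esiRNA replicate 1.

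Target genes of p53 rose in part, with 6 of 23 past the threshold with the term and 13 adjusted over the list alone. GDF15 went from 50.56 ± 14.72 to 141.6 ± 22.02 CPM (SD, n = 3 each), SESN1 rose by 0.92 on the log2 scale, and CDKN1A (p21) did not pass at a log2 fold change of 0.57 (SE 0.15). The p53 list had a camera adjusted p with Benjamini-Hochberg adjustment of 1.15e-06, against an adjusted p = 0.549 with an estimated correlation and 0.213 by fry, and with the term 2.61e-05, 0.435 and 0.0387. Without control replicate 1, 16 rose and 2 fell. The number that rose was at most 2 without any 1 of control replicates 2 and 3 and EPHB2 esiRNA replicates 2 and 3.

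Of the NF-kB and inflammatory cytokine genes, 5 of 26 rose with the term and 7 adjusted over the list alone. The chemokine genes CXCL5 and CXCL8 rose by 3.23 and 1.49 and BIRC3 by 2.88 on the log2 scale. The list median was 0.13 in set 1 and 1.71 in set 2. This list had a camera adjusted p with Benjamini-Hochberg adjustment of 0.00221, against an adjusted p = 0.629 with an estimated correlation and 0.482 by fry, and with the term 2.61e-05, 0.663 and 0.174. Without EPHB2 esiRNA replicate 1 the camera adjusted p was 0.63, and 0.291 with the term, and the number that rose was 22, 2 and 2 without control replicates 1, 2 and 3 and 2 without EPHB2 esiRNA replicate 2.

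Unfolded protein and integrated stress response genes fell in part, with 4 of 28 past the threshold with the term, 24 not, and 5 past it adjusted over the list alone. Among them were PHGDH and PSAT1, enzymes of serine synthesis, which fell by 1.31 and 1.45 on the log2 scale, and CHAC1 and DNAJC3, which fell by 0.90 and 0.57. The chaperone gene HSPA5 did not pass, at a log2 fold change of -0.23 (SE 0.16). Their camera adjusted p with Benjamini-Hochberg adjustment was 0.00537, against an adjusted p = 0.629 with an estimated correlation and 0.289 by fry, and with the term 0.00643, 0.809 and 0.268. Without EPHB2 esiRNA replicate 1 it was 0.12, and 0.679 with the term, and the number that fell was 18 without control replicate 1 and at most 2 without any 1 of control replicates 2 and 3 and EPHB2 esiRNA replicates 2 and 3.

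Other Eph receptors and ephrins moved in both directions. Among 14 tested members, EPHB2 included, EPHA2 and EFNA5 rose by 0.99 and 1.18 on the log2 scale with the library set term. EPHB3 fell by 1.05 along with EPHB2. EPHA4 rose too, and EPHA3 and EFNA3, all 3 named after their values were seen, fell as well, the latter pair at a few CPM, which makes 3 higher and 4 lower, and adjusted over the list alone 3 higher and 5 lower. The list's camera p with Benjamini-Hochberg adjustment was 0.187, and 0.319 with the term, and without EPHB2 esiRNA replicate 1 it was 0.0464 without the term. With the term EPHB2 was the 1 member lower without any 1 of control replicates 2 and 3 and EPHB2 esiRNA replicates 2 and 3. At most 1 member was higher in these fits.

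Among the TGF-beta and PDGF ligands and receptors, 3 of 22 rose and 3 fell with the term, and 4 were higher and 5 lower adjusted over the list alone. The type II receptor gene TGFBR2 rose by 1.38, endoglin (ENG) by 0.73 and ACVRL1 by 1.88 on the log2 scale. PDGFD fell by 1.14, and BMPR1A and PDGFA, named after their values were seen, fell too. TGFB1 and PDGFRB did not pass, at log2 fold changes of -0.01 (SE 0.26) and -0.56 (SE 0.16). The type I receptor gene TGFBR1 had a log2 difference of 1.32 in set 1 and -0.95 in set 2. For this list the camera adjusted p with Benjamini-Hochberg adjustment was 0.852, and 0.934 with the term. Without control replicate 1, 8 were higher and 13 lower, and without EPHB2 esiRNA replicate 1, 7 were higher and 3 lower. At most 2 passed without any 1 of control replicates 2 and 3 and EPHB2 esiRNA replicates 2 and 3.

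Several lists had members that went both ways with the term and no list call by camera or by fry for movement one way. The mixed form of fry asks for movement in either direction and does not compare a list with other genes. With the term it gave these lists Benjamini-Hochberg adjusted p values from 1.37e-05 to 0.000242, and it passed most other lists too. YAP/TAZ and SRF targets had 3 of 31 higher, among them NT5E, IER2 and AXL, and 4 lower, among them GADD45B (5 higher and 9 lower adjusted over the list alone, camera adjusted p with Benjamini-Hochberg adjustment 0.278). Of the quiescent stellate cell genes, NT5E, PPARG and CYGB rose and NGFR fell, with 3 of 22 higher and 3 lower (6 and 5 adjusted over the list alone, 0.983). These 22 were the genes tested of 35 listed. LRAT, RGS5, GFAP and LHX2 were among those below the count filter, so the list result does not cover them. Axon guidance genes had 3 of 28 higher, namely SEMA3A, PLXNB1 and SEMA4C, and UNC5C lower (4 and 1 adjusted over the list alone, 0.476). Among 30 hypoxia and glycolysis genes ANGPTL4 rose by 3.96 on the log2 scale, CA12 rose and EGLN3 fell (2 and 1 adjusted over the list alone, 0.427). TNRC6B rose and TNRC6C fell among 13 genes of RNA interference machinery (1 and 2 adjusted over the list alone, 0.934). Without control replicate 1, 9 quiescent stellate cell genes and 9 axon guidance genes were higher and 10 hypoxia genes lower. That fit also had 7 YAP/TAZ and SRF targets higher and 6 lower, and 3 genes of RNA interference machinery higher and 4 lower. Without EPHB2 esiRNA replicate 1, 7 quiescent stellate cell genes and 6 axon guidance genes were lower. In these lists at most 4 were higher and 2 lower without any 1 of control replicates 2 and 3 and EPHB2 esiRNA replicates 2 and 3. The hypoxia list had a camera adjusted p with Benjamini-Hochberg adjustment of 0.044 without EPHB2 esiRNA replicate 1 in the test without the term. In that test NT5E was the 1 gene past the threshold among the 571 tested members of the lists, 181 had an unadjusted p under 0.05, and DESeq2 called 101.

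Proliferation and cholesterol synthesis lists had at most 2 members past the threshold each. With the term AURKA rose among the 15 cell division genes tested of 30 listed (1 adjusted over the list alone). The remaining listed genes were below the count filter. The median log2 difference of those tested was -0.07 in set 1 and 0.705 in set 2. MCM5 rose and CCNE2 fell with the term among 29 DNA replication genes (1 higher and 0 lower adjusted over the list alone). INSIG1 rose with the term among 25 cholesterol synthesis genes (1 adjusted over the list alone). The cell division genes had 4 higher and 1 lower, the DNA replication genes 4 and 3 and the cholesterol synthesis genes 3 and 2 without control replicate 1. Without EPHB2 esiRNA replicate 1, 7 cholesterol synthesis genes were higher and 1 lower, and without any 1 of the other 4 libraries at most 1 member of each list passed. Camera adjusted p values with Benjamini-Hochberg adjustment were 0.967, 0.335 and 0.932, and with the term 0.478, 0.589 and 0.0184, the last against an adjusted p = 0.663 with an estimated correlation, 0.241 without control replicate 1 and 0.064 without EPHB2 esiRNA replicate 2. For mitochondrial transcripts, edgeR called 0 of 13 with or without the term, DESeq2 called 0 without and 1 lower with it, and the unadjusted p was under 0.05 for 0 and 1. The camera adjusted p of this list was 0.856, and 0.0593 with the term, and its median was 0.11 in set 1 and -0.78 in set 2. It was 0.00502 without EPHB2 esiRNA replicate 1, in the higher direction, and with the term 3.36e-05 without control replicate 1 (9 members lower) and 0.027 without EPHB2 esiRNA replicate 2, both in the lower direction. Median, mean and test directions differed in sign in at least 1 fit for the quiescent stellate cell, cross-linking enzyme, YAP/TAZ and SRF, TGF-beta and PDGF, cell division, cholesterol synthesis, hypoxia and cholangiocyte lists.

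Hepatocyte markers and most leukocyte markers were near the floor of detection, while some endothelial, cholangiocyte and epithelial markers, CD68 and CD74 were above it. Of 19 hepatocyte markers 3 were abundant enough to test, CPS1 being the highest at 1.85 ± 1.21 CPM in controls and 1.14 ± 1.22 CPM with EPHB2 esiRNA (SD, n = 3 each), and edgeR called 0 of them with the term and DESeq2 0, with 1 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone. Of 17 endothelial markers 8 were tested and ROBO4 rose, from 0.68 to 1.74 CPM (2 higher and 1 lower adjusted over the list alone). FLT1, the most abundant of them, had 24.6 ± 15.4 CPM in controls and 11.4 ± 13.5 CPM with EPHB2 esiRNA (SD, n = 3 each) and did not pass. Of 21 macrophage and leukocyte markers 5 were tested and CD14 rose, from 0.13 to 0.93 CPM (3 higher adjusted over the list alone), with CD68 at 0.69 and 4.76 CPM not past the threshold. CD74, at 1.17 CPM in controls and 3.96 CPM with EPHB2 esiRNA, did not pass either, and it reached 10.5 CPM in EPHB2 esiRNA replicate 1. Among 9 tested cholangiocyte and epithelial markers KRT8 and KRT18 fell by 1.16 and 2.12 on the log2 scale, KRT7 fell from 14.5 to 2.89 CPM and SOX9 rose by 0.87 (1 higher and 3 lower adjusted over the list alone). Camera adjusted p values with Benjamini-Hochberg adjustment were 0.856, 0.206, 0.00959 and 0.187 for the 4 lists in this order, and with the term 0.59, 0.0794, 0.00358 and 0.472. The macrophage and leukocyte call had an adjusted p = 0.261 with an estimated correlation, and 0.435 with the term, and without the term it was lost without control replicate 1 (0.112) and EPHB2 esiRNA replicate 1 (0.0596). Leaving out control replicate 1 gave 4 endothelial, 2 leukocyte and 5 cholangiocyte markers higher with the term, with CD14 not past the threshold. Leaving out EPHB2 esiRNA replicate 1 gave 2 endothelial markers lower, with ROBO4 not past the threshold, and 2 cholangiocyte markers higher and 4 lower. Neither ROBO4 nor CD14 passed without any 1 of the other 4 libraries. The cholangiocyte list passed without EPHB2 esiRNA replicate 1 (0.0172, and 0.0293 with the term), and the endothelial list with the term without control replicate 1 (0.0287). Camera with an estimated correlation passed no list, with adjusted p values from 0.205 to 0.987 without the term and from 0.435 to 0.989 with it. The preset correlation of 0.01 passed 10 and 11 of 26 lists and fry 3 and 6. Without the term the estimated correlation was 0.545 for NF-kB, 0.504 for p53, 0.331 for stress response and 0.257 for contractile genes. It was 0.064 for the TGF-beta response, 0.00408 for matrix glycoproteins, -0.00595 for smooth muscle markers, -0.0157 for matrix proteases and -0.144 for leukocyte markers.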

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

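The library set term, its alternatives and the surrogate variable were chosen after seeing the data, and the other settings were fixed before. EPHB2 was lower in every setting. When 1 library was left out, its log2 fold changes ran from -2.82 to -2.20 without the set term and from -2.68 to -1.88 with it. EPHB2 passed the threshold without a low-count filter (-2.40), with DESeq2 (-2.39), with the set term (-2.28) and with the surrogate variable (-2.45). That variable came from the same counts and ran from -0.467 to -0.315 in set 1 and from 0.265 to 0.622 in set 2. It divides the libraries as the sets do, so its calls are not separate from those with the set term. The numbers of genes higher and lower were 99 and 77 without a low-count filter, 545 and 419 with DESeq2, 913 and 801 with the set term, 1261 and 1255 with the surrogate variable, and 12 higher under a minimum fold of 1.2. Leaving out 1 library gave 0 to 202 higher and 0 to 165 lower. RLE size factors, library totals and the stricter filter stayed within 1.5 times of the main counts.

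Libraries with the same replicate number deviated from their group means in opposite directions, with correlations across genes of -0.576, -0.381 and -0.485. These values give no sign of pairing by number. They are not independent of each other, because the deviations within a group balance out, and the labels do not say what the number marks. With a replicate block edgeR called 0 genes higher and 0 lower, with 1348 at an unadjusted p under 0.05.

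With the set term, 2160 genes were higher and 1821 lower without a low-count filter, 1431 and 1267 with DESeq2, and 528 and 443 under a minimum fold of 1.2. Leaving out 1 library gave 175 to 2828 higher and 168 to 2896 lower. Without control replicate 1 or EPHB2 esiRNA replicate 1, a set holds libraries of 1 group only and the contrast rests on the other set. There 1 of the groups has a single library, and the fits use fewer libraries. Without a low-count filter 19 TGF-beta response genes, 7 collagens, 17 matrix glycoproteins and 23 contractile genes were lower. Leaving out 1 library gave 1 to 21, 1 to 12, 1 to 16 and 4 to 21 lower in these lists, and 22 to 41 interferon-stimulated genes higher.

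Adjusted p values of the list tests with an estimated correlation were 0.535 for the TGF-beta response, 0.205 for matrix glycoproteins, 0.472 for contractile and 0.451 for interferon-stimulated genes, and with the set term 0.663, 0.435, 0.663 and 0.435. By fry they were 0.236 for the TGF-beta response and 0.0701 for contractile and interferon-stimulated genes, and with the set term 0.12 for the first and for contractile genes. The collagen list passed with library totals (0.0282) and without a low-count filter (0.0193). Leaving out 1 library gave 0.00101 to 0.246 for collagens and 0.00148 to 0.205 for the TGF-beta response, and with the set term 0.0292 to 0.689 and 0.000338 to 0.299. With the set term TGFBR1 and SERPINE2 reversed without control replicate 1 (log2 fold changes from -0.948 to 1.32 and from -0.626 to 1.24 over the left-out libraries) and TGFB1 reversed without EPHB2 esiRNA replicate 1 (from -0.537 to 0.517). No other named gene past the threshold in either of the fits compared changed sign in a setting run. The cause of these changes was not tested beyond the number of genes or libraries a setting leaves.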

Other observations

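The lists of ERK feedback, metallothionein and class I genes were written after changed genes had been seen, and the tests of swapped labels, immune cells, replicate 1 alone, double-stranded RNA, metallothioneins and other divisions of the libraries were chosen after the result was seen.

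Genes that ERK signalling switches on, among them its feedback inhibitors, rose in part with EPHB2 esiRNA. With the library set term 11 of 20 rose and 0 fell (13 higher and 1 lower adjusted over the list alone), with log2 fold changes of 2.45 for the phosphatase gene DUSP6, 2.15 for FOSL1, 1.72 for DUSP4 and 0.98 for SPRY4. The hypothesis that these genes rise together gave p = 1.91e-08 by camera, p = 0.00872 with an estimated correlation and 6.48e-05 by fry. Without the term 2 of 20 passed over all genes and 8 adjusted over the list alone, and the p with an estimated correlation was 0.0224, or 0.0671 adjusted over the 3 lists. Metallothionein genes, which bind zinc and copper, rose in all 3 tested members with the term, with MT2A going from 81.5 ± 39.6 to 554 ± 175 CPM (SD, n = 3 each) and MT1E by 2.25 on the log2 scale. The hypothesis of a joint rise gave camera p = 3.16e-05, p = 0.0246 with an estimated correlation and fry p = 2e-05, over genes of near-identical sequence. Without the term edgeR called 0 of 3 over all genes and 3 adjusted over the list alone, 3 had an unadjusted p under 0.05, DESeq2 called 3, and the p with an estimated correlation was 0.0527, or 0.079 adjusted over the 3 lists. These lists were picked because some of their genes had been seen to change, so their p-values do not decide whether each set rises as a whole.

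Genes of class I antigen presentation rose in part. With the term 6 of 18 rose and 0 fell (16 adjusted over the list alone), among them TAP2 by 2.37, TAP1 by 2.64 and PSMB8 by 2.25 on the log2 scale, and the list median was 0.38 in set 1 and 2.7 in set 2, which holds EPHB2 esiRNA replicate 1. Without the term edgeR called 0 over all genes and 12 adjusted over the list alone, 13 had an unadjusted p under 0.05 and DESeq2 called 7. The hypothesis of a joint rise gave camera p = 2.26e-08 and fry p = 0.0441, but p = 0.222 with an estimated correlation, and this list too was picked after changed genes had been seen. IFNB1, the gene of interferon beta, had 0 counts in each control library and 33, 5 and 3 counts in EPHB2 esiRNA replicates 1 to 3. The 3 interferon lambda genes together had 0 counts in each control library and 3, 1 and 0 counts.

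Of the 10 ways to divide 6 libraries into 3 and 3, 2 called at least the 30 genes of the real groups, and the highest other, with 3161 genes, was the division into the library sets, which points to a structure of the samples but is no separate evidence of it, since the sets come from the first principal component of the same counts. The remaining 8 called 0 genes in edgeR, with 57 to 415 at an unadjusted p under 0.05. Swapped labels of control replicate 1 and EPHB2 esiRNA replicate 1 are argued against by EPHB2, which was 3.19 times higher in the former, and unequal depth by the 3051 genes still called between the sets after thinning to the smallest total. A difference in culture, passage or donor may underlie the sets and was not tested, since the labels give none.

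Within the sets, the real labels called 1714 genes, and the other 8 of the 9 arrangements called 0 at most, with 47 to 922 at an unadjusted p under 0.05, so that 1 of 9 reached the real count. Neither 10 divisions nor 9 arrangements can give a share under 0.05. The hypothesis that the same genes respond in both sets, which share no library, was tested by the correlation across genes of their log2 differences, which was 0.494 for the real labels and between -0.469 and 0.371 for the others. The other arrangements still hold part of the group difference in their sets, so they are no reference free of it. The rank of 0.494 among them therefore does not decide the hypothesis. Genes are not independent replicates.

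Interferon-stimulated genes were higher in every EPHB2 esiRNA library. Immune cells among the cells are argued against by 12 abundant leukocyte transcripts, whose highest median in an EPHB2 esiRNA library was 0.0161 CPM, although SRGN, which stellate cells also express here, was between 48.4 and 307 CPM in all libraries. Replicate 1 alone is argued against by the median log2 difference of 3.36 in set 1, which does not hold that library. A response to the EPHB2 esiRNA as a double-stranded RNA cannot be told apart from a consequence of the loss of EPHB2, because no library has the reagent without the loss. EPHB2 esiRNA replicates 1 to 3 kept 28.4%, 14.6% and 13.7% of the control mean of EPHB2. Their mean log2 CPM of the list was 8.20, 5.25 and 4.93, so the library with the most EPHB2 left had the highest list. This rests on replicate 1, which lies in the other library set, and does not decide between the 2 explanations. The lowest EPHB2 esiRNA library lay 2.50 above the highest control in mean log2 CPM, and the control esiRNA is itself double-stranded, so a candidate explanation is a difference between the pools in sequence, dose or purity.

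Contractile genes fell in part with EPHB2 esiRNA. Scaling between libraries is argued against by the list median, whose highest value under RLE size factors or library totals was -0.513 without the library set term and -0.497 with it. Whether the interferon response lowers these genes stays open and cannot be told apart from an effect of EPHB2. The fall was larger by -0.352 in set 2, where the median of the interferon list was higher by 2.35, but each set holds 3 libraries and they differ in other ways.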
